A study of Mus musculus with 8 samples.

How the data were processed

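Kidney libraries of polyadenylated RNA from ICR mice, 4 after BPA and 4 after vehicle, were compared. The deposited table gives FPKM (reads scaled by gene length and by a library size) for 54532 genes, with gene lengths, coordinates and biotypes, and the authors made these values from their reads. Per the submitters' processing notes, DESeq2 1.20.0 and the genome build GRCm38 were used, with no role stated. The aligner and the read counter are not given in the sources used here, nor is the handling of reads with several matches. The columns of the table named for BPA match the BPA libraries by name. The other columns carry a letter and a number and were taken as vehicle, the only other group in the labels, with the number as the replicate.

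In each library, FPKM times gene length was a whole multiple of 1 step, within 0.01 reads, in 100% of low values (those of up to 20 steps), so the authors counted whole reads. Recovered reads were 15944081 to 17351540 per library. The library size behind the deposited FPKM equalled the median-ratio size factor times the mean read total, so the values are scaled between libraries by the median ratio and not by each library's own total. A mean of 0.5 FPKM, the filter used here, rests on few reads for short genes, and low genes are measured with more counting error than high ones. Of the gene identifiers, 54495 were found in GENCODE release M21 and 53585 had the same coordinates there. The symbols of 102 names are shared by more than 1 identifier. GC content came from the longest annotated transcript and was known for 99.91% of tested genes. Processed pseudogenes were aligned to protein-coding transcripts with blastn 2.17.0 (e-value 1e-20), and 699 of 725 tested ones had a parent.

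The comparison of single genes used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trended, robust empirical Bayes variance and no covariate, over the 13376 genes (11550 protein-coding) with a mean of at least 0.5 FPKM over the 8 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Changes are on the log2(FPKM + 1) scale, which understates the change of low genes. No count model was used for the main result because the deposited values are FPKM. Gene lists were tested with camera from limma, with a preset inter-gene correlation of 0.01, over the 49 lists with at least 5 tested members, and again with an estimated correlation. Fry, also from limma, tested whether a list's genes moved on balance one way, without comparing them with other genes. Members were counted after adjustment over all genes and adjusted over the list alone. The levels of 20 marker lists (mean log2 per library) and library measures were compared with a 2-sided exact permutation test over the 70 assignments of 4 of 8 libraries, whose smallest p is 0.0286. Similarity of libraries was described by principal components and Pearson correlations. No pair of libraries within a group was a duplicate: the chi-square of recovered reads per gene was 14.3 to 91.0.

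The test, its samples, the filter, the pseudocount, the gene lists, the marker lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named up to 10 called genes per direction, leaving out clone names and predicted genes; where fewer than 5 passed, the 5 with the smallest p were given as not passing. In each list described, up to 4 called members or otherwise up to 2 members with the smallest p were named, and a fixed set of steroid, receptor, early response and injury genes was always given. Some genes that this rule names are not reported here. A gene that several parts of the rule name is described where it first fits. On simulated data drawn from these libraries, with 200 of 13376 genes changed, limma called 34.5% of genes changed 2-fold, 80% of those changed 4-fold and 88% of those changed 8-fold, with 1, 9 and 13 unchanged genes called. Camera made 5 false calls in 50 unchanged data sets of 49 lists, drawn without correlation between genes, and called the immediate early list in 50 of 50 when it was shifted by -0.5.

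Alternatives were other pseudocounts and filters, scaling by median ratio, to a common total or by quantiles, library weights, other variance models, limma-voom on recovered reads, protein-coding genes only, a minimum change, a replicate block, and each library left out in turn. A term for replicates 1 and 2 against 3 and 4, a clock covariate, a correction for GC and leaving out both replicates 4 were chosen after seeing the data. Calculations outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Reads, other tissues and the metabolite measurements named in the title were not analysed here.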

Results

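RNA sequencing of polyadenylated transcripts measured gene expression in mouse kidney after exposure to bisphenol A (BPA), a monomer of polycarbonate plastics and a weak ligand of estrogen receptors, or to vehicle. Each group had 4 libraries, and their names give the mice as ICR, an outbred stock. Dose, route, duration and age are not given in the sources used here. Whole read numbers recovered from the deposited FPKM values gave 15944081 to 17351540 reads per library, and the totals of the groups overlapped (exact permutation p = 0.914). The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. Ddx3y, a gene of the Y chromosome, was at 10.3 to 14.5 FPKM in the libraries. Uty, also of the Y chromosome, was at 2.79 ± 0.0441 FPKM in vehicle and 3.36 ± 0.298 FPKM in BPA. Xist, expressed from the inactive X chromosome, was at 0.0304 FPKM or less.

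The libraries differed in ways other than their group. Pearson correlations of log2(FPKM + 1) between libraries ran from 0.913 to 0.979. BPA replicate 4 stood apart on the first principal component, which held 33.2% of the variance, with a score of 57.5 against -4.70 to 4.08 in the other BPA libraries. That library also had the fewest genes above 0, 17174 against 19090 to 20502 in the other BPA libraries and 19693 to 20845 in vehicle. Vehicle replicate 4 carried skeletal muscle transcripts: Acta1, the actin of skeletal muscle, was at 103 FPKM there and at 0 in every other library, while fat transcripts were found in several libraries. The adipocyte hormone Adipoq was at 22.2 FPKM in vehicle replicate 4, 7.17 in vehicle replicate 2, 2.53 in vehicle replicate 3 and at most 1.87 FPKM in the others, and Ucp1, of brown fat, at 7.18 FPKM in vehicle replicate 2 and 1.41 FPKM in vehicle replicate 4. Several clock genes divided replicates 1 and 2 of both groups from replicates 3 and 4. Others did not, such as the repressor gene Nr1d1 (3.57 and 15.2 against 6.13 and 6.18 FPKM in vehicle). Arntl, which encodes the activator BMAL1, was at 2.22 to 4.27 FPKM in replicates 1 and 2 and at 0.106 to 0.55 FPKM in replicates 3 and 4, whereas its output gene Dbp was at 0.876 to 9.02 FPKM and at 22.4 to 44.2 FPKM. For the steroid hormone list and the called lists below, the change is therefore also given within each of these parts of the libraries, which were seen in the data and are not groups of the study.

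Mitochondrially encoded transcripts took 7.41 ± 0.615% of reads in vehicle and 10.9 ± 2.20% in BPA (SD, n = 4). The share was higher in all 4 BPA libraries than in any vehicle library (2-sided exact permutation p = 0.0286, the smallest this design allows, and 0.0857 after Benjamini-Hochberg adjustment over 6 library measures). BPA replicate 4 had the highest share, 14.2%. The GC content of transcripts also moved with the group: across genes, which are not independent replicates, the Spearman correlation of the BPA change with GC was -0.40. Per library, the correlation of a gene's deviation from its mean with GC averaged 0.207 ± 0.0546 in vehicle and -0.197 ± 0.109 in BPA (exact permutation p = 0.0286, adjusted p = 0.0857).

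The comparison of BPA with vehicle asked first which single transcripts differed. Gm8430, a processed pseudogene (ENSMUSG00000055093), was the only 1 of 13376 tested genes to pass limma's test, and it fell by 1.13 on the log2(FPKM + 1) scale (SE 0.0892, adjusted p = 0.00745). Its level was 14.7 ± 1.01 FPKM in vehicle and 6.17 ± 0.288 FPKM in BPA (SD, n = 4), lower in 4 of 4 BPA libraries than the vehicle mean. It was outside the rule for named genes and was chosen after its values were seen, as the only gene called. The gene is a single exon on chromosome 6 from 122456904 to 122457374 of GRCm38, on the plus strand, inside an intron of Rimklb, which lies on the minus strand and was at 0.0969 FPKM or less. Its 471 bases aligned to the transcript of Rps27a, the gene of a ubiquitin and ribosomal protein fusion, with 1 mismatch (99.8% identity), so the assignment of reads between the pseudogene and Rps27a is uncertain. Rps27a itself had a log2 change of -0.12. The smallest adjusted p among the other genes was 0.171, and 1473 genes had an unadjusted p under 0.05 (559 higher and 914 lower in BPA), where 668.8 would be so by chance. The call was lost without vehicle replicate 1, vehicle replicate 3 or BPA replicate 2 (adjusted p = 0.0695, 0.0707 and 0.0619), where limma called 0 genes beside 1167, 1099 and 1685 with an unadjusted p under 0.05. Limma-voom on the recovered reads called 0 genes beside 1507, and limma with a replicate block 0 beside 1376 (smallest adjusted p = 0.196). Without both replicates 4 the call of Gm8430 was lost as well (adjusted p = 0.0520), and the 1 gene called was the pseudogene Rpsa-ps10, higher by 2.59. The count was 2 without vehicle replicate 2 or BPA replicate 4, 3 without vehicle replicate 4 or BPA replicate 1, 4 without BPA replicate 3, and 8 with limma's library weights.

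No other gene passed, and those with the smallest p in each direction are given as values. Among those lower in BPA, Amn, which encodes the membrane partner of cubilin in protein uptake by the proximal tubule, was at 142 ± 7.98 FPKM in vehicle and 79.8 ± 6.31 FPKM in BPA (log2 change -0.83, SE 0.107, limma adjusted p = 0.171). Jun, a subunit of the transcription factor AP-1, was at 11.8 ± 2.07 and 5.53 ± 0.845 FPKM (log2 change -0.97, SE 0.147, adjusted p = 0.218). Dapk3, a death-associated kinase, had a log2 change of -0.74, the zinc finger gene Zfp771 of -0.82, and the pseudogene Rpsa-ps2 of -1.24. Rpsa-ps2 aligned to Rpsa with 98.8% identity, so its reads are uncertain as well. Among those higher in BPA, Aldh1a1, an enzyme of retinoic acid synthesis, was at 0.681 ± 0.232 FPKM in vehicle and 6.47 ± 3.31 FPKM in BPA (log2 change 2.04, SE 0.317, adjusted p = 0.218). Sc5d, a late enzyme of cholesterol synthesis, went from 2.99 ± 0.435 to 4.88 ± 0.453 FPKM, and Gpr155, a lysosomal cholesterol sensor, from 3.67 ± 0.266 to 5.63 ± 0.5 FPKM. The mitochondrial tRNA gene mt-Tn (log2 change 1.37) and the immunoglobulin segment Ighv1-19 (log2 change 1.35) completed the 5. Transcript GC content was 55.5 to 68.7% in the 5 named as lower and 33.8 to 49.4% in the 5 named as higher. With library weights, Amn, Rpsa-ps2, Dapk3, Jun and Zfp771 passed as lower and Aldh1a1 as higher. Without BPA replicate 3, Aldh1a1 passed (adjusted p = 0.0318), and without vehicle replicate 4, Rpsa-ps2 (adjusted p = 0.0312).

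**Figure D1:**
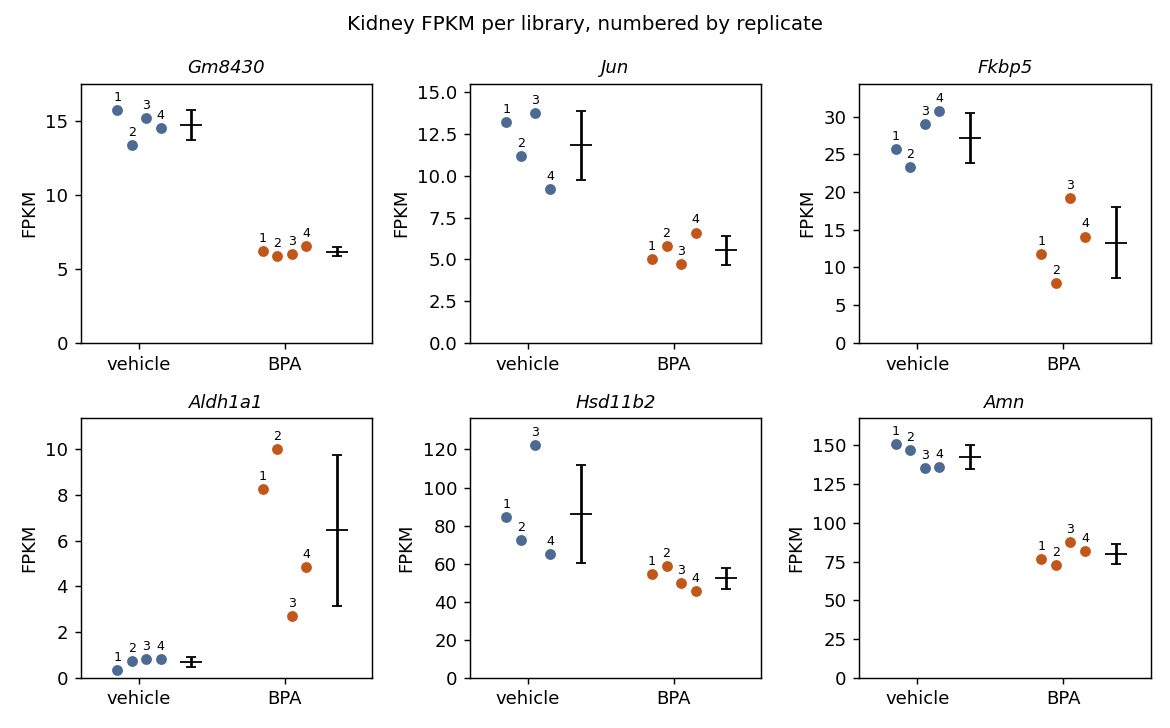
FPKM per library of Gm8430, Jun, Fkbp5, Aldh1a1, Hsd11b2 and Amn in vehicle and BPA kidney; each point is a library, and the line and bar are the mean and SD of 4 libraries. Gm8430, the only gene called by limma, went from 14.7 ± 1.01 to 6.17 ± 0.288 FPKM, and the other genes shown did not pass.

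Steroid hormone metabolism, a theme named in the title of the series, was compared over a list of enzymes fixed before the data were examined. Of 25 tested members, 13 were higher and 12 lower in BPA, with a median log2 change of 0.04 (camera adjusted p = 0.727), so the list was not called. Its median was 0.13 within replicates 1 and 2 and -0.00 within replicates 3 and 4. Adjusted over all genes, 0 members passed limma's test, and adjusted over the list alone also 0, beside 1 higher and 3 lower at an unadjusted p under 0.05. Hsd11b2, which inactivates corticosterone in the collecting duct, was at 86.1 ± 25.6 FPKM in vehicle and 52.3 ± 5.57 FPKM in BPA (log2 change -0.67, SE 0.195, adjusted p = 0.365). Hsd11b1, which regenerates corticosterone, was at 67.2 ± 42.7 and 44.8 ± 26.2 FPKM (adjusted p = 0.646), with 131 FPKM in vehicle replicate 4. Its log2 change of -0.67 turned to 0.25 without both replicates 4. Hsd3b4, a hydroxysteroid dehydrogenase, was at 1.34 ± 0.253 and 4.87 ± 2.60 FPKM (adjusted p = 0.387) and passed only without BPA replicate 3, whose level was 0.975 FPKM (log2 change 1.62, adjusted p = 0.0177). Star, which delivers cholesterol to the mitochondrion, was at 0.640 ± 0.164 and 0.839 ± 0.197 FPKM. The steroid synthesis enzymes Cyp17a1, with 22 reads over the vehicle libraries and 28 over BPA, and Cyp21a1, with 3 and 1, were too low to test, and Cyp11a1 had 0 reads in both groups. The direction of the list turned without vehicle replicate 3 (-0.02), vehicle replicate 4 (-0.02) or BPA replicate 1 (-0.01), and its median was 0.08 without vehicle replicate 1 and 0.09 without BPA replicate 3. The median was 0.14 with quantile normalization and without both replicates 4, 0.11 with a clock covariate and 0.08 after GC correction.

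Hormone receptors were likewise compared as a list, of which 13 members were higher and 8 lower (median log2 change 0.12, camera adjusted p = 0.397), with 0 members passing limma's test over all genes or over the list alone and 3 higher and 1 lower at an unadjusted p under 0.05. The receptor median was 0.04 without BPA replicate 4, 0.05 without vehicle replicate 3 and -0.00 without both replicates 4. The glucocorticoid receptor Nr3c1 was at 14.0 ± 0.928 FPKM in vehicle and 18.5 ± 3.11 FPKM in BPA (adjusted p = 0.387). Esrrg, an estrogen-related receptor that binds BPA, was at 11.3 ± 1.10 and 14.5 ± 2.45 FPKM (log2 change 0.33, adjusted p = 0.429), and the estrogen receptor Esr1 at 1.97 ± 0.482 and 2.70 ± 0.204 FPKM (log2 change 0.33, adjusted p = 0.429). Both were above the vehicle mean in 4 of 4 BPA libraries. Genes of the male kidney that depend on androgen had 10 members higher and 12 lower (adjusted p = 0.680); their median change was -0.07, while their mean (0.02) and the test pointed up. When each library was left out, their median ran from -0.16 without BPA replicate 3 to 0.06 without BPA replicate 4. Their transporter Slc22a28 had a log2 change of 0.25 (adjusted p = 0.496). Female-biased kidney genes had 10 higher and 5 lower (median 0.21, adjusted p = 0.0582), and 1 member, Aldh1a1, passed when adjusted over the list alone. Another member, the transporter Slc22a29, was at 0.418 ± 0.184 and 1 ± 0.442 FPKM (adjusted p = 0.425). The female-biased list was called without vehicle replicate 3 (median 0.38, adjusted p = 0.00512), without a filter on low values (0.27, adjusted p = 0.0151), after rescaling to a common total (0.15, adjusted p = 0.0372) and with library weights (0.21, adjusted p = 0.0386). Its median was 0.08 without BPA replicate 3 (adjusted p = 0.185) and 0.04 at a mean of at least 5 FPKM (adjusted p = 0.601).

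MAPK signalling, the other theme of the title, was compared in its cascade and in its transcriptional targets. Cascade components were not called: 41 of 72 tested members were higher and 31 lower, with a median log2 change of 0.08 (camera adjusted p = 0.304) and 0 members passing limma's test over all genes or adjusted over the list alone, beside 7 higher and 5 lower at an unadjusted p under 0.05. Srf, a transcription factor that ERK signalling activates through its partners, was at 11 ± 1.12 and 7.47 ± 0.854 FPKM (adjusted p = 0.313), and the receptor Fgfr4 at 18.2 ± 1.26 and 12.8 ± 2.04 FPKM (adjusted p = 0.355). The cascade median was 0.04 without vehicle replicate 3, 0.03 without vehicle replicate 4, 0.03 without BPA replicate 4 and 0.01 without both replicates 4. It was 0.03 after rescaling to a common total and 0.02 with library weights.

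MAPK transcriptional targets and immediate early genes, which respond within minutes to growth factors and stress, fell as a list: 26 of 32 tested members were lower, with a median log2 change of -0.46 (camera adjusted p = 2.68e-06). The value was adjusted p = 0.478 with an estimated correlation and 0.104 by fry. The median was -0.44 within replicates 1 and 2 and -0.43 within replicates 3 and 4. Members that passed as lower numbered 9 adjusted over the list alone and 0 over all genes, beside 12 lower and 0 higher at an unadjusted p under 0.05. Jun was at 11.8 ± 2.07 and 5.53 ± 0.845 FPKM, and its relative Junb at 8.05 ± 2.49 and 3.23 ± 0.307 FPKM (log2 change -1.06, SE 0.182, adjusted p = 0.271). The fixed members Fos (1.82 ± 1.75 and 0.333 ± 0.208 FPKM, adjusted p = 0.463), Egr1 (3.56 ± 3.76 and 0.542 ± 0.321 FPKM, adjusted p = 0.432) and the MAPK phosphatase Dusp1 (17.7 ± 7.61 and 10.7 ± 3.30 FPKM, adjusted p = 0.477) did not pass. Vehicle replicate 2 held the highest Egr1 (8.98 FPKM) and Fos (4.04 FPKM); without it their log2 changes were -0.74 in place of -1.23 and -0.53 in place of -0.88. The median GC content of the list was 54.5%. Without a filter on low values the list's median was -0.27, with adjusted p = 2.40e-07.

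Glucocorticoid-responsive genes fell as well, with 20 of 23 tested members lower and a median log2 change of -0.51 (camera adjusted p = 0.00041; adjusted p = 0.478 with an estimated correlation and 0.104 by fry). Within replicates 1 and 2 the median was -0.29, and within replicates 3 and 4 it was -0.44. A single test of each member called 1 as lower adjusted over the list alone and 0 over all genes, beside 7 lower and 1 higher at an unadjusted p under 0.05. Fkbp5, a cochaperone that restrains the glucocorticoid receptor, was at 27.2 ± 3.31 and 13.3 ± 4.71 FPKM (log2 change -1.03, SE 0.229, adjusted p = 0.306). The transcription factor Cebpb was at 21.2 ± 7.14 and 7.24 ± 4.20 FPKM (log2 change -1.54, adjusted p = 0.365). The list's median was -0.33 without both replicates 4 (adjusted p = 0.00147).

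Both stress lists fell too. In the unfolded protein response list 22 of 29 members were lower, with a median log2 change of -0.23 (camera adjusted p = 0.0052; adjusted p = 0.5 with an estimated correlation and 0.106 by fry). Of its members, 1 passed as lower adjusted over the list alone and 0 over all genes, beside 6 lower and 0 higher at an unadjusted p under 0.05. Its chaperone Creld2 was at 34.2 ± 9.02 and 16.4 ± 3.33 FPKM (adjusted p = 0.271), and the ubiquitin ligase Syvn1 at 12.8 ± 1.58 and 8.83 ± 1.44 FPKM (adjusted p = 0.365). In the heat shock list 14 of 19 members were lower, with a median of -0.29 (camera adjusted p = 0.00507; adjusted p = 0.715 with an estimated correlation and 0.478 by fry). Of its members, 3 passed as lower adjusted over the list alone and 0 over all genes, beside 5 lower and 0 higher at an unadjusted p under 0.05. The cochaperone Bag3 was at 13.3 ± 2 and 8.9 ± 1.2 FPKM (adjusted p = 0.335), and Hspa1a, the inducible HSP70, at 1.13 ± 0.522 and 0.296 ± 0.0765 FPKM (adjusted p = 0.355). The medians within replicates 1 and 2 and within replicates 3 and 4 were -0.30 and -0.22 for the first list and -0.37 and -0.22 for the second. The heat shock call was lost without vehicle replicate 1 (median -0.20, adjusted p = 0.0762).

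**Figure D2:**
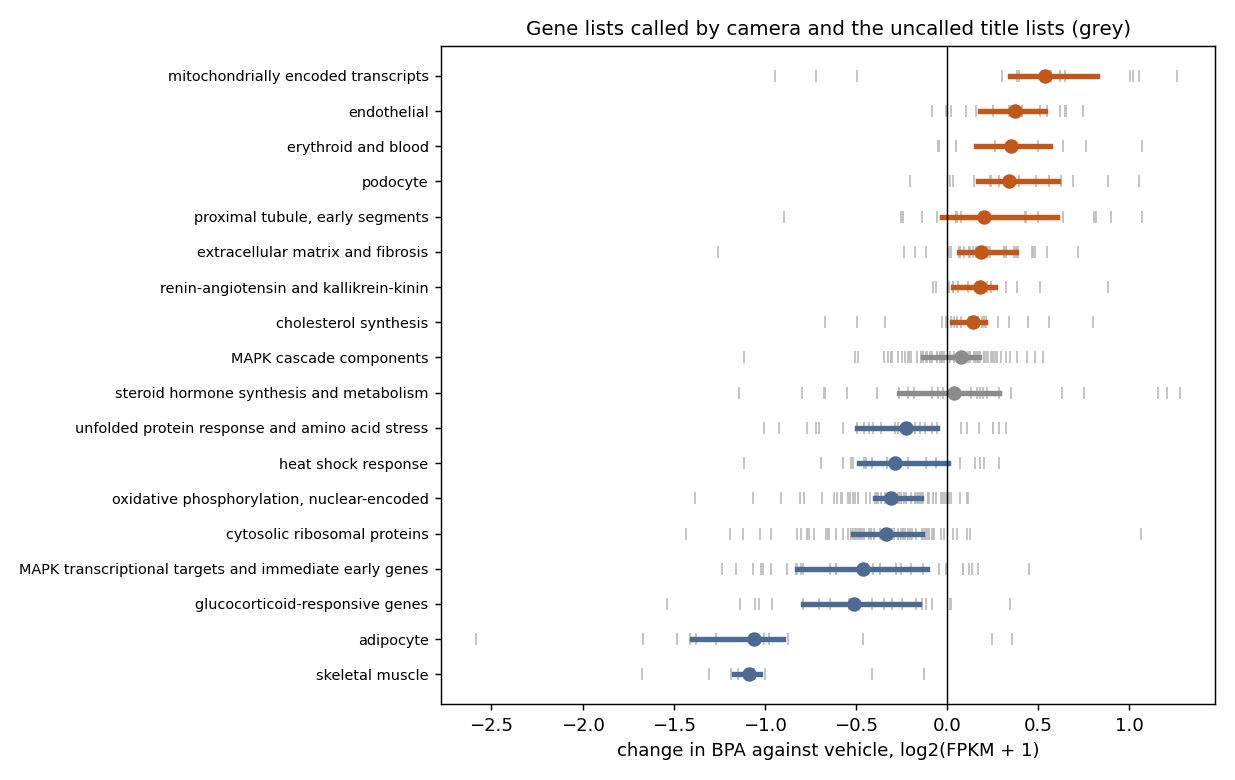
Log2 change of BPA against vehicle, on the log2(FPKM + 1) scale, in the 16 called lists and, in grey, the steroid hormone and MAPK cascade lists that were not called; ticks are members, the dot is the median and the bar the interquartile range. The immediate early list sits at a median of -0.46 and the mitochondrially encoded list at 0.54, and 0 lists were called by camera with an estimated correlation or by fry.

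Mitochondrially encoded transcripts and nuclear-encoded genes of the respiratory chain were each compared between the groups. The mitochondrially encoded list also holds the ribosomal RNAs mt-Rnr1 and mt-Rnr2. Mitochondrially encoded transcripts rose, with 12 of 15 members higher and a median log2 change of 0.54 (camera adjusted p = 2.37e-05; adjusted p = 0.708 with an estimated correlation and 0.274 by fry). Nuclear-encoded subunits of oxidative phosphorylation fell, with 68 of 74 members lower and a median of -0.31 (adjusted p = 6.06e-07; adjusted p = 0.784 with an estimated correlation and 0.689 by fry). The difference between the lists was not tested. Cytosolic ribosomal protein genes fell, with 68 of 73 lower and a median of -0.33 (adjusted p = 2.28e-09; adjusted p = 0.777 with an estimated correlation and 0.591 by fry). Adjusted over the list alone, 9 mitochondrially encoded members passed as higher and 0 members of the other lists; over all genes limma called 0 in each, beside 9 higher and 1 lower, 6 lower and 17 lower at an unadjusted p under 0.05. The complex I subunit mt-Nd1 was at 10536 ± 486 FPKM in vehicle and 15392 ± 1993 FPKM in BPA (adjusted p = 0.359), and mt-Nd2 at 5606 ± 533 and 8672 ± 1593 FPKM (adjusted p = 0.365). The complex I subunit Ndufa2 was at 177 ± 28.4 and 104 ± 24.8 FPKM (adjusted p = 0.355), and Ndufa8 at 113 ± 12.6 and 88.6 ± 6.78 FPKM (adjusted p = 0.393). The ribosomal protein gene Rpl24 was at 3.07 ± 0.252 and 0.906 ± 0.779 FPKM (adjusted p = 0.321), and Rpsa at 150 ± 15.6 and 107 ± 12.7 FPKM (adjusted p = 0.365). Rpl24 was low for its list, whose mean log2 level in vehicle was 5.97, and was at 0 FPKM in BPA replicate 4. The median GC content was 36.0% for mitochondrially encoded transcripts, 50.2% for oxidative phosphorylation and 51.0% for ribosomal proteins. The mitochondrially encoded list had medians of 0.35 within replicates 1 and 2 and 0.73 within replicates 3 and 4, but the falls did not hold within replicates 1 and 2, at 0.04 for oxidative phosphorylation and 0.07 for ribosomal proteins against -0.61 and -0.72 within replicates 3 and 4. Without BPA replicate 4 these medians were -0.07 and -0.14 (adjusted p = 0.0267 and 5.37e-05), and without both replicates 4 they were -0.06 and -0.08. In BPA replicate 4 the Spearman correlation of a gene's deviation from its mean with gene length was 0.409, against -0.253 to 0.134 in the other libraries. Whether gene length bears on the falls of oxidative phosphorylation and ribosomal protein genes was not tested. Library weights ended the oxidative phosphorylation call (median -0.07, adjusted p = 0.0532) and left the ribosomal median at -0.11. With quantile normalization the oxidative phosphorylation median was -0.20. Quantile normalization ended the call of mitochondrially encoded transcripts (median 0.27, adjusted p = 0.140).

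**Figure D3:**
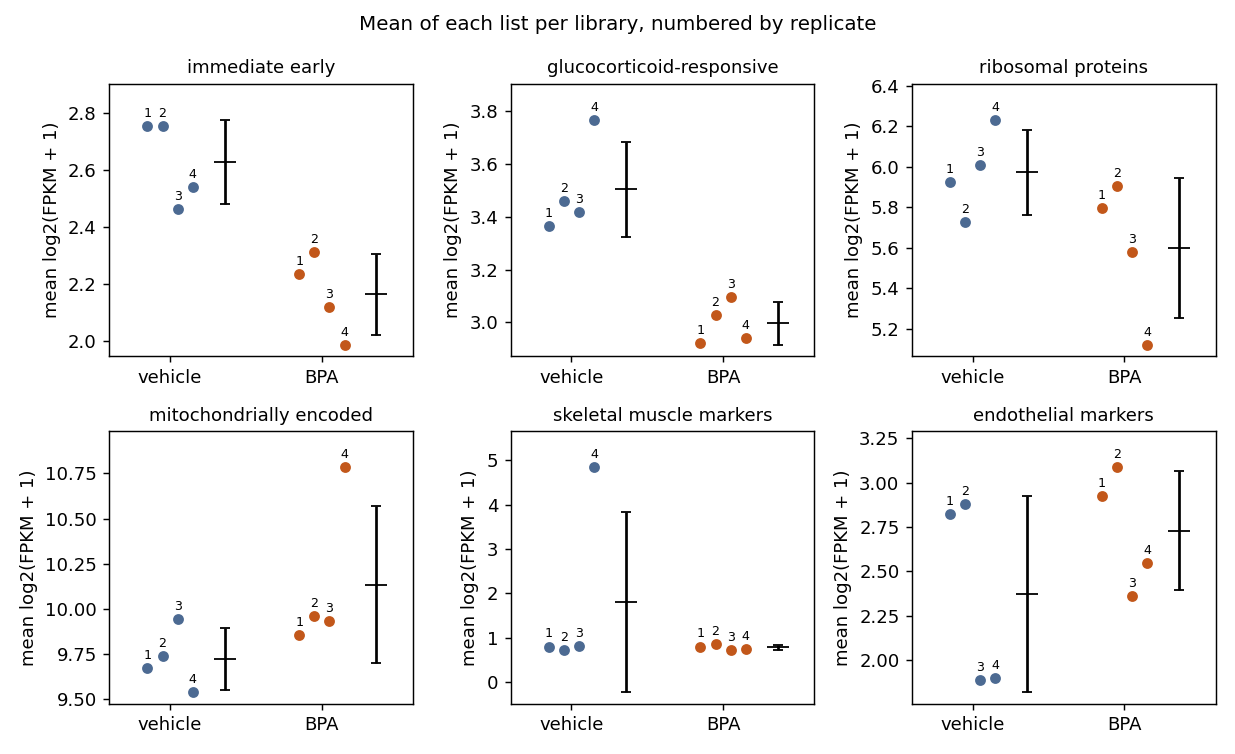
Mean log2(FPKM + 1) over the members of 6 lists in each library of vehicle and BPA kidney; each point is a library, and the line and bar are the mean and SD of 4 libraries. Immediate early genes were at 2.63 ± 0.149 in vehicle and 2.16 ± 0.142 in BPA, vehicle replicate 4 was at 4.84 for skeletal muscle, and BPA replicate 4 was at 10.8 for mitochondrially encoded transcripts.

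Markers of cell types were compared to ask whether the makeup of the tissue differed. The mean level of each marker list per library could not settle this, because an exact permutation test of 4 against 4 gives no p under 0.0286. Over 20 lists a single list at that p has an adjusted p of 0.571, and most lists would have to reach it for any to pass. That 0 of 20 lists passed is therefore no evidence of a like makeup. The 1 list with an unadjusted p under 0.05 was thin limb: its markers were at 4.21 ± 0.115 in vehicle and 3.90 ± 0.0960 in BPA on the log2(FPKM + 1) scale (exact permutation p = 0.0286). Thin limb had only 4 of 10 markers tested, 1 higher and 3 lower in BPA, too few for camera. Its members Cldn4, a tight junction claudin (5.98 ± 0.414 and 4 ± 0.876 FPKM), and Akr1b3, the aldose reductase (13.8 ± 3.28 and 9.89 ± 1.61 FPKM), did not pass over all genes, and 1 member passed as lower when adjusted over the list alone. Camera, which sets a list against the other genes, called 6 marker lists.

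Markers of the glomerulus and vessels were higher by that test. Podocyte markers rose, with 13 of 14 members higher and a median log2 change of 0.34 (camera adjusted p = 0.00115; adjusted p = 0.708 with an estimated correlation and 0.478 by fry). Adjusted over the list alone 2 members passed as higher and over all genes 0, beside 3 at an unadjusted p under 0.05. The peptidase Dpp4 was at 7.92 ± 2.49 and 15 ± 1.6 FPKM (adjusted p = 0.321), and the chloride channel protein Clic3 at 2.02 ± 0.362 and 3.48 ± 0.843 FPKM (adjusted p = 0.365). Endothelial markers rose, with 16 of 18 higher and a median of 0.37 (adjusted p = 0.00385; adjusted p = 0.784 with an estimated correlation and 0.705 by fry); 0 members passed limma's test over all genes or adjusted over the list alone, beside 2 at an unadjusted p under 0.05. Ehd3, a marker of glomerular endothelium, was at 2.79 ± 1.2 and 4.78 ± 0.823 FPKM (adjusted p = 0.387), and Nrp1, a coreceptor of VEGF, at 3.91 ± 0.812 and 6.14 ± 2.09 FPKM (adjusted p = 0.432). Within replicates 1 and 2 the medians were 0.04 for podocyte and 0.18 for endothelial markers, and within replicates 3 and 4 they were 0.65 and 0.63. The podocyte call was lost with library weights (median 0.15, adjusted p = 0.0532), and without both replicates 4 the podocyte median was 0.17 (adjusted p = 0.0469). It was larger at a mean of at least 5 FPKM (0.63), with a pseudocount of 0.1 (0.55) and with limma-voom (0.58). The endothelial call was lost without vehicle replicate 3 (median 0.18, adjusted p = 0.119), vehicle replicate 4 (0.22, adjusted p = 0.0726) or BPA replicate 2 (0.24, adjusted p = 0.101), and without both replicates 4 the endothelial median was 0.22 (adjusted p = 0.0412).

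Early proximal tubule markers rose, with 13 of 18 members higher and a median of 0.20 (camera adjusted p = 0.0391; adjusted p = 0.777 with an estimated correlation and 0.641 by fry), at -0.02 within replicates 1 and 2 and 0.51 within replicates 3 and 4. The secreted protein gene Spp2 was at 43.1 ± 15.8 and 88.4 ± 15.5 FPKM (adjusted p = 0.321), and the acetyltransferase Nat8 at 294 ± 116 and 153 ± 43.3 FPKM (adjusted p = 0.408). Adjusted over the list alone 1 member passed as higher and over all genes 0, beside 3 higher and 1 lower at an unadjusted p under 0.05. The call was lost without vehicle replicate 1 (median 0.20, adjusted p = 0.0581), BPA replicate 3 (0.15, adjusted p = 0.226) or BPA replicate 4 (0.15, adjusted p = 0.181), and the median was 0.32 without BPA replicate 2. It was also lost with rescaling to a common total, quantile normalization, library weights, a clock covariate or both replicates 4 left out (adjusted p = 0.0513, 0.136, 0.229, 0.0742 and 0.0949).

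Erythroid and blood genes rose, with 9 of 11 members higher and a median of 0.35 (camera adjusted p = 0.00503; adjusted p = 0.478 with an estimated correlation and 0.265 by fry), at 0.32 within replicates 1 and 2 and 0.45 within replicates 3 and 4. Alas2, the enzyme that starts heme synthesis in red cell precursors, was at 2.08 ± 0.888 and 6.41 ± 4.95 FPKM (adjusted p = 0.440). Adjusted over the list alone 1 member passed as higher and over all genes 0, beside 2 at an unadjusted p under 0.05. The call was lost without BPA replicate 2 (median 0.29, adjusted p = 0.0761) or with a filter at a mean of 5 FPKM (adjusted p = 0.0720), and the median was 0.17 without both replicates 4.

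Adipocyte and skeletal muscle markers fell, and neither call held when vehicle replicate 4 was left out. Adipocyte markers had 12 of 14 members lower and a median of -1.06 (camera adjusted p = 0.0118; adjusted p = 0.784 with an estimated correlation and 0.641 by fry), at -0.67 within replicates 1 and 2 and -1.53 within replicates 3 and 4. All 11 skeletal muscle markers were lower, with a median of -1.09 (adjusted p = 0.0391; adjusted p = 0.792 with an estimated correlation and 0.705 by fry), but the median was 0.03 within replicates 1 and 2 and -2.21 within replicates 3 and 4. In both lists 0 members passed limma's test over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. The lipid droplet gene Plin4 was at 1.71 ± 2 and 0.245 ± 0.220 FPKM and the adipocyte hormone Retn at 2.59 ± 2.64 and 0.473 ± 0.559 FPKM. Pvalb, which the distal convoluted tubule also expresses, was at 77.1 ± 27.4 and 54.9 ± 7.58 FPKM, and Actn3, a muscle actinin, at 16.6 FPKM in vehicle replicate 4 and at most 0.208 FPKM in the other vehicle libraries. Without vehicle replicate 4 the adipocyte median was -0.55 (adjusted p = 0.121) and the muscle median 0 (adjusted p = 0.822). The adipocyte call was also lost without vehicle replicate 2 (-0.86, adjusted p = 0.0752), BPA replicate 2 (-0.98, adjusted p = 0.0761) or BPA replicate 4 (-0.99, adjusted p = 0.0779). The muscle call was lost without BPA replicate 1 (-1.09, adjusted p = 0.0665), 2 (-1.11, adjusted p = 0.0825), 3 (-1.06, adjusted p = 0.106) or 4 (-1.07, adjusted p = 0.0652). Rescaling to a common total, library weights, limma-voom and leaving out both replicates 4 ended both calls (adipocyte adjusted p = 0.0591, 0.173, 0.0721 and 0.383; muscle adjusted p = 0.131, 0.177, 0.0860 and 0.865). The adipocyte call was also lost at a mean of at least 5 FPKM (adjusted p = 0.954), and the muscle call without a filter and with vooma weights (adjusted p = 0.0560 and 0.0695). With a pseudocount of 0.1 the medians were -2.10 and -1.78.

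Matrix, pressor and sterol genes were the remaining lists called, each higher in BPA. Extracellular matrix genes rose, with 26 of 30 members higher and a median of 0.19 (camera adjusted p = 0.0052; adjusted p = 0.784 with an estimated correlation and 0.705 by fry). The collagen Col14a1 was at 3.88 ± 2.22 and 6.43 ± 1.10 FPKM (adjusted p = 0.453), whereas Cyr61, a matrix protein that immediate early signals induce, was at 19.7 ± 11.8 and 7.32 ± 4.49 FPKM (adjusted p = 0.444). Renin-angiotensin and kallikrein-kinin genes rose, with 14 of 16 higher and a median of 0.18 (adjusted p = 0.0141; adjusted p = 0.708 with an estimated correlation and 0.478 by fry). The angiotensin II receptor Agtr1a was at 13.0 ± 3.08 and 18.7 ± 2.58 FPKM (adjusted p = 0.385). Dpp4 and Enpep are listed both here and as podocyte markers, so the calls of these lists are not independent. Cholesterol synthesis genes rose, with 18 of 23 higher and a median of 0.14 (adjusted p = 0.0437; adjusted p = 0.708 with an estimated correlation and 0.478 by fry). Besides Sc5d, the isomerase Idi1 was at 13.8 ± 6.01 and 23.8 ± 6.42 FPKM (adjusted p = 0.408). Over all genes 0 members of these lists passed; adjusted over the list alone 0 matrix, 1 renin-angiotensin and 1 cholesterol gene passed as higher, beside 1 higher and 1 lower, 3 higher, and 2 higher and 1 lower at an unadjusted p under 0.05. The medians within replicates 1 and 2 and within replicates 3 and 4 were 0.02 and 0.40 for matrix, 0.13 and 0.15 for renin-angiotensin, and 0.16 and 0.07 for cholesterol genes. The matrix call was lost without vehicle replicate 3 (0.13, adjusted p = 0.126), vehicle replicate 4 (0.14, adjusted p = 0.141) or BPA replicate 2 (0.15, adjusted p = 0.0761), with library weights (0.12, adjusted p = 0.0532) and at a mean of at least 5 FPKM (adjusted p = 0.214). It had a median of 0.31 without vehicle replicate 1. The renin-angiotensin call was lost without vehicle replicate 4 (0.01, adjusted p = 0.121), BPA replicate 2 (0.11, adjusted p = 0.0545) or BPA replicate 3 (0.22, adjusted p = 0.0678), with 0.28 without vehicle replicate 3. The cholesterol call was lost without vehicle replicate 1 (0.11, adjusted p = 0.0587), vehicle replicate 4 (0.09, adjusted p = 0.117), BPA replicate 1 (0.08, adjusted p = 0.288) or BPA replicate 2 (0.08, adjusted p = 0.127). It was also lost at a mean of at least 5 FPKM, after rescaling to a common total, with protein-coding genes only and without both replicates 4 (adjusted p = 0.0516, 0.0513, 0.0557 and 0.0549), and the matrix call without both replicates 4 (adjusted p = 0.241). The renin-angiotensin median was 0.06 without a filter on low values and 0.09 without both replicates 4. The matrix median was 0.34 with a pseudocount of 0.1, 0.38 with limma-voom and 0.32 after GC correction.

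Kidney injury and defence lists were not called. Tubule injury genes had 13 of 30 members higher and a median of -0.14 (camera adjusted p = 0.641). Havcr1, the injury marker KIM-1, was at 1.97 ± 0.781 and 1.51 ± 0.348 FPKM (adjusted p = 0.649). The stress cytokine Gdf15 was at 5.4 ± 2.35 and 1.98 ± 0.42 FPKM (adjusted p = 0.355), and Spp1, osteopontin, at 131 ± 60.6 and 224 ± 36.8 FPKM (adjusted p = 0.408). The injury marker Lcn2 had 41 reads over the vehicle libraries and 39 over BPA and was too low to test. Xenobiotic phase I enzymes had 16 of 26 higher and a median of 0.19 (adjusted p = 0.0634), with the monooxygenase Fmo5 at 6.11 ± 1.27 and 15 ± 5.82 FPKM (adjusted p = 0.355). Aldh1a1 was the 1 member of that list to pass when adjusted over the list alone. The phase I list was called without vehicle replicate 3 (median 0.20, adjusted p = 0.00532), vehicle replicate 4 (0.14, adjusted p = 0.0363) or BPA replicate 1 (0.16, adjusted p = 0.0365). Its median was smaller without BPA replicate 4 (0.10, adjusted p = 0.308), without vehicle replicate 1 (0.11, adjusted p = 0.263) and without a filter on low values (0.06). Phase II conjugation enzymes, among which are those that glucuronidate BPA, had 20 of 32 lower and a median of -0.07 (adjusted p = 0.826), with Gsto1, a glutathione transferase, at 4.85 ± 1.15 and 6.58 ± 0.596 FPKM. NRF2 targets had 20 of 30 lower (median -0.09, adjusted p = 0.377), with Keap1, which holds NRF2 in check, at 8.44 ± 0.755 and 6.81 ± 0.308 FPKM and Gclc, of glutathione synthesis, at 75.3 ± 9.47 and 94 ± 5.24 FPKM. Inflammatory cytokines had 10 of 19 lower (median -0.08, adjusted p = 0.866), with Il34, a macrophage growth factor, at 30.9 ± 2.36 and 22.2 ± 6.32 FPKM and the chemokine Ccl21a at 1.1 ± 1.03 and 0.0368 ± 0.0737 FPKM. Interferon-stimulated genes had 18 of 35 lower (median -0.04, adjusted p = 0.705), with Ifi27 at 19.7 ± 6.89 and 10.5 ± 1.66 FPKM and the GTPase Igtp at 8.5 ± 1.3 and 6.25 ± 0.227 FPKM. When each library was left out, the median ran from -0.16 (without BPA replicate 2) to -0.08 (without vehicle replicate 1) for tubule injury and from -0.12 (without BPA replicate 1) to 0.04 (without BPA replicate 4) for phase II enzymes. It ran from -0.15 (without vehicle replicate 4) to 0.01 (without BPA replicate 4) for NRF2 targets. Without BPA replicate 2 it was -0.14 for cytokines and -0.09 for interferon-stimulated genes, and it reached 0.00 for cytokines without BPA replicate 1 and 0.06 for interferon-stimulated genes without vehicle replicate 2. Among these lists 0 members passed limma's test over all genes, beside 3 or fewer per direction in each at an unadjusted p under 0.05.

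Metabolic, transport and stress lists not described above were not called either, with 0 members passing limma's test over all genes and 3 or fewer per direction in each, except the clock list with 5 lower, at an unadjusted p under 0.05. Renal drug and metabolite transporters had 23 of 33 higher (median 0.14, camera adjusted p = 0.0634), with the efflux pump Abcg2 at 64.5 ± 5.47 and 80.1 ± 6.54 FPKM. Slc22a18 was lower in BPA, at 398 ± 44.1 and 319 ± 22.1 FPKM. That list was called without vehicle replicate 3 (median 0.15, adjusted p = 0.00532) or BPA replicate 1 (0.14, adjusted p = 0.0226), without a filter on low values (0.14, adjusted p = 0.0162) and with quantile normalization (0.20, adjusted p = 0.0264). Its median was smaller without vehicle replicate 4 (0.08, adjusted p = 0.141). It was 0.08 after rescaling to a common total, 0.09 at a mean of at least 5 FPKM, and 0.07 with library weights and without both replicates 4. Fatty acid oxidation genes had 24 of 39 lower (median -0.10, adjusted p = 0.529), with the lipase inhibitor Angptl4 at 11 ± 4.83 and 4.81 ± 2.34 FPKM and the hydroxylase Cyp4a12b at 2.27 ± 0.734 and 6.45 ± 3.47 FPKM. Fatty acid synthesis genes had 12 of 20 lower (median -0.07, adjusted p = 0.680), with the elongase Elovl5 at 12.9 ± 1.16 and 16.1 ± 2.9 FPKM. The carboxylase Acacb was at 2.86 ± 0.528 and 2.07 ± 0.623 FPKM. Amino acid metabolism had 29 of 52 lower (median -0.03, adjusted p = 0.865), with Acmsd, of tryptophan breakdown, at 104 ± 31.3 and 161 ± 32.6 FPKM. Bckdha, of branched-chain amino acid breakdown, was at 42.9 ± 3.53 and 34.4 ± 3.72 FPKM. Gluconeogenesis and glycolysis had 17 of 31 lower (adjusted p = 0.936), with a median of -0.01 and a mean of -0.02 while the test pointed up, and the coactivator Ppargc1a was at 6.8 ± 1.1 and 9.5 ± 1.43 FPKM. The glucose transporter Slc5a1 was at 14.9 ± 2.87 and 18.9 ± 0.957 FPKM. Aldosterone and sodium transport genes had 12 of 23 lower (adjusted p = 0.680), with a median and mean of -0.02 while the test pointed up, and the potassium channel Kcnj16 was at 301 ± 29.8 and 388 ± 38.6 FPKM. Without both replicates 4 the aldosterone list was called as lower (median -0.22, adjusted p = 0.0129). Hypoxia genes had 16 of 22 lower (median -0.07, adjusted p = 0.252), with the angiogenic factor Vegfa at 36.6 ± 4.23 and 28 ± 3.44 FPKM. Ddit4, an inhibitor of mTORC1 signalling, was at 11.2 ± 6.12 and 4.34 ± 1.93 FPKM. Genes of p53 and apoptosis had 15 of 26 higher (adjusted p = 0.964), with a median of 0.01 while their mean (-0.08) and the test pointed down, and Ccng1, a p53 target, was at 74 ± 9.02 and 103 ± 16.7 FPKM. Cell cycle genes (median 0.08, adjusted p = 0.377; cyclin Ccnd1 at 19.2 ± 5.96 and 27.1 ± 9.42 FPKM, ribonucleotide reductase Rrm2 at 1.14 ± 0.4 and 0.683 ± 0.332 FPKM) and replication-dependent histones (median -0.13, adjusted p = 0.517; Hist1h4h at 4.24 ± 1.42 and 1.46 ± 1.16 FPKM, Hist1h2be at 1.98 ± 0.542 and 3.56 ± 1.42 FPKM) were not called. Without both replicates 4 the cell cycle list was called (median 0.16, adjusted p = 0.0412). Clock genes had 15 of 24 lower (median -0.09, adjusted p = 0.328). Their repressor Cry1, at 3.5 ± 1.26 and 0.926 ± 0.341 FPKM (adjusted p = 0.271), did not pass over all genes, and 1 member passed as lower adjusted over the list alone. With a clock covariate the clock list was called as lower (median -0.15, camera adjusted p = 0.0126). That covariate is the mean of Dbp, Tef, Per2, Per3, Nr1d1 and Ciart less that of Arntl, Npas2 and Clock. These are members of the list itself, so no conclusion is drawn from that call.

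The medians of these metabolic and stress lists moved with single libraries. Without vehicle replicate 1 they were lowest for fatty acid oxidation (-0.17), fatty acid synthesis (-0.15) and clock genes (-0.25), and the highest were -0.01 without vehicle replicate 3, 0.04 without vehicle replicate 2 and 0.11 without BPA replicate 1. Without vehicle replicate 4 they were lowest for amino acid metabolism (-0.09), gluconeogenesis (-0.04) and histones (-0.24), and the highest were 0.01 without vehicle replicate 3, 0.02 without BPA replicate 1 and -0.05 without BPA replicate 4. Aldosterone genes ran from -0.13 without BPA replicate 4 to 0.12 without BPA replicate 2, and hypoxia genes from -0.10 without BPA replicate 2 to -0.06 without vehicle replicate 3. The p53 list ran from -0.03 without BPA replicate 1 to 0.04 without vehicle replicate 2. Cell cycle genes ran from 0.04 without vehicle replicate 1 to 0.13 without vehicle replicate 4.

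Of the tubule markers not called, thick ascending limb had 10 of 12 members higher (median 0.24, camera adjusted p = 0.0502), with Cldn19, a claudin of magnesium reabsorption, at 2.97 ± 1.1 and 4.09 ± 0.398 FPKM. Sostdc1, an inhibitor of BMP signalling, was at 20.6 ± 6.57 and 27.1 ± 2.77 FPKM. The thick ascending limb list was called without vehicle replicate 1 (median 0.32, adjusted p = 0.0221), vehicle replicate 2 (0.29, adjusted p = 0.0391), vehicle replicate 3 (0.43, adjusted p = 0.000996) or BPA replicate 3 (0.36, adjusted p = 0.0140). It was also called after rescaling to a common total, with library weights, limma-voom, a clock covariate or GC correction (adjusted p = 0.0283, 0.0462, 0.0307, 0.0182 and 0.0246). Its median turned to -0.01 without vehicle replicate 4 and to -0.03 without both replicates 4. Distal convoluted and connecting tubule had 8 of 13 higher (median 0.11, adjusted p = 0.567), with the calcium-binding protein Calb1 at 59.5 ± 26.7 and 90.2 ± 38.8 FPKM. The median of that list was -0.07 without BPA replicate 4, 0.01 without vehicle replicate 4 and 0.14 without vehicle replicate 1. The magnesium channel Trpm7 was at 11.9 ± 1.42 and 15.9 ± 3.07 FPKM. Straight proximal tubule had 9 of 15 higher (median 0.10, adjusted p = 0.591), with the amino acid transporter subunit Slc3a1 at 184 ± 12.9 and 216 ± 42.5 FPKM. The straight segment median was 0.01 without BPA replicate 2, 0.03 without vehicle replicate 2, 0.05 without vehicle replicate 4 and 0.15 without vehicle replicate 3. The hydroxylase Cyp7b1 was at 40.6 ± 33.6 and 73.5 ± 55.8 FPKM. Principal cells had 8 of 12 lower (median -0.09, adjusted p = 0.413), with the water channel Aqp2 at 84.2 ± 43 and 47.1 ± 15.7 FPKM. That list was called as lower without vehicle replicate 4 (median -0.15, adjusted p = 0.0268) and without both replicates 4 (-0.26, adjusted p = 0.00853). Its median was -0.18 without BPA replicate 4 and turned to 0.04 without vehicle replicate 3. Intercalated cells had 9 of 15 lower (adjusted p = 0.984), with a median of -0.07 and a mean of -0.01 while the test pointed up, and the proton pump subunit Atp6v0d2 was at 8.64 ± 2.44 and 12.2 ± 3.16 FPKM. That median ran from -0.18 without vehicle replicate 4 to 0.01 without vehicle replicate 3. The anion exchanger Slc4a1 was at 3.39 ± 0.711 and 4.7 ± 1.17 FPKM. Fibroblast markers had a median of 0.12 (adjusted p = 0.187; Col3a1 at 1.87 ± 1.25 and 2.98 ± 0.785 FPKM, Pdgfra at 0.941 ± 0.612 and 1.55 ± 0.347 FPKM), macrophage markers of -0.14 (adjusted p = 0.690; S100a9 at 3.46 ± 2.32 and 1.01 ± 1.09 FPKM) and lymphocyte markers of -0.33 (adjusted p = 0.233; Cd8a at 1.26 ± 0.41 and 0.543 ± 0.77 FPKM, Trbc1 at 2.48 ± 3.47 and 0.294 ± 0.289 FPKM). Of the macrophage markers Cx3cr1 was higher in BPA, at 0.706 ± 0.375 and 1.19 ± 0.372 FPKM. Fibroblast markers were called as higher without vehicle replicate 2 (median 0.18, adjusted p = 0.0391), without BPA replicate 3 (0.17, adjusted p = 0.0261) and with a clock covariate (0.11, adjusted p = 0.0398). Their median was 0.05 without BPA replicate 4 (adjusted p = 0.540) or vehicle replicate 1 (adjusted p = 0.0882). Without vehicle replicate 3, macrophage and lymphocyte markers were called as lower (-0.35 and -0.49, adjusted p = 0.0317 for each). Without vehicle replicate 4 these medians were 0.09 and -0.03 (adjusted p = 0.670 and 0.531). Vehicle replicate 4 had the highest lymphocyte level of all libraries (mean log2 3.34) and BPA replicate 4 the lowest (1.34), so the lymphocyte shift rested on both. In contrast, without both replicates 4 the lymphocyte list was called as higher (0.31, adjusted p = 0.00853) and macrophage markers were at 0.17. Markers of tissue beside the kidney were not called for adrenal cortex (median 0.16, adjusted p = 0.591; Fdx1 at 26.5 ± 4.2 and 19.6 ± 6.79 FPKM, Akr1c18 at 8.45 ± 9.71 and 17.1 ± 17.3 FPKM), adrenal medulla and nerve (0.09, adjusted p = 0.400; Slc18a1 at 26.1 ± 4.98 and 38.1 ± 11 FPKM, Ddc at 12.5 ± 6.47 and 16.7 ± 4.64 FPKM) or liver (0.40, adjusted p = 0.377; Alb at 2.93 ± 1.06 and 7.17 ± 3.45 FPKM). Left-out libraries moved these medians from 0.04 (without BPA replicate 1) to 0.23 (without BPA replicate 4) for adrenal cortex and from -0.00 (without BPA replicate 4) to 0.27 (without vehicle replicate 4) for adrenal medulla. For liver they moved from 0.27 (without BPA replicate 2) to 0.58 (without BPA replicate 4). The liver gene Hp was lower in BPA, at 3.72 ± 3.82 and 0.577 ± 0.688 FPKM. Only 5 of 16 markers were tested for adrenal cortex, 5 of 16 for adrenal medulla and nerve and 6 of 17 for liver. Among the untested adrenal cortex markers, Cyp11a1 had 0 reads and Cyp21a1 had 3 reads over vehicle and 1 over BPA. The levels of the tested adrenal members are therefore not taken as a measure of adrenal tissue. Over all genes limma called 0 members of these lists, and adjusted over the list alone also 0, beside at most 1 per direction in each at an unadjusted p under 0.05. Besides thin limb, too few members for the list test were found for pancreas and gut (Vil1, an actin bundler of brush borders, at 59 ± 2.47 and 62.1 ± 4.83 FPKM, and Cela1 at 27.9 ± 3.48 and 21.8 ± 7.4 FPKM) and for urothelium (Krt7 at 6.82 ± 2.5 and 6.08 ± 1.22 FPKM).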

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

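Tests chosen only after the result was seen were the comparison of Gm8430 with its parent gene, the test of a gene variant, the clock covariate, the GC correction of the immediate early list and the term for replicates 1 and 2 against 3 and 4.

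The fall of Gm8430 came with lower values of ribosomal protein pseudogenes. Over 73 such pseudogenes the median change less that of the parent was -0.0158 (95% interval -0.151 to 0.131), so reads shared with the parent at a constant rate remain a candidate explanation for the class. For Gm8430 itself the change less that of Rps27a was -1.01 (SE 0.220, exact permutation p = 0.0286). Gm8430 was chosen for its fall, so this difference is large by its selection and the p adds nothing. Rps27a, which was not so chosen, was at 30.2 to 40.7 FPKM in vehicle and 24.0 to 42.8 FPKM in BPA. Only these parent values, which did not fall likewise, argue against such sharing there. The larger range inside a group was 0.192 of the difference between groups, but a gene that alone passed has a small range by its selection, so a variant cannot be told apart. Other processed pseudogenes fell by 0.0990 more than matched coding genes (interval -0.149 to -0.0622), and the value was -0.0772 (-0.121 to -0.0441) for those without a ribosomal protein parent. A difference in read assignment between the groups may therefore contribute, and an effect of BPA was not separated from it. The intervals given for pseudogenes are taken over genes with the libraries held fixed, so they hold no spread between libraries.

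The BPA change fell with transcript GC content across genes, which are not independent replicates. The correlation was -0.44 in protein-coding genes, -0.24 in processed pseudogenes and -0.244 in lincRNA and antisense genes, which is consistent with a GC bias of the libraries. Gene length as the source of this GC trend was argued against, since the weakest correlation inside groups of genes of like length was -0.306. So was BPA replicate 4 as the only source, since the correlation without it was -0.437. A biological cause was not excluded.

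The immediate early and glucocorticoid lists were lower in BPA in both parts of the libraries divided by several clock genes. With a clock covariate the median of the immediate early list was -0.444, 96.1% of its size (interval 76.5 to 109%, camera adjusted p = 1.29e-05). The covariate ran from -1.06 to 2.70 in vehicle and from -0.502 to 3.10 in BPA. The groups overlapped in it, so it could remove little of a difference between them. This argues against clock state as the cause only as far as the covariate measures it. Clock differences outside it, as in Cry1 and Nfil3, were not tested as a cause. After a GC correction it was -0.358 (77.5% kept, interval 49.3 to 89.4%; adjusted p = 1.45e-05), and the glucocorticoid list was at -0.37, so a part due to GC bias cannot be told apart, because the interval is wide. Without vehicle replicates 1 and 2 the early list was at -0.336 (72.8% kept, interval 12.4 to 108%, camera adjusted p = 0.0212), so their share cannot be told apart either. The intervals of the share kept resample the genes of the list with the libraries held fixed. They treat genes as independent and hold no spread between libraries. An effect of BPA and of handling before collection stay open, the latter untested.

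Other splits of the 8 libraries into 4 and 4 show what chance can give. Of 35 splits, 6 called at least as many genes as the real one (1 gene, highest other 51) and 8 at least as many lists (16 lists, highest other 22), so chance was not excluded for either count. The median number of lists called over the other splits was 13. At an unadjusted p under 0.05 the real split had 1473 genes, and of the others only that of replicates 1 and 2 from 3 and 4 had more (1594, next highest 1191). For the camera p of the immediate early list, only the real split, 1 of 35, was as small (1.64e-07, smallest other 5.30e-07), which puts the share under 0.05 for this list alone, with no adjustment for the other lists. That share is the smallest that 35 splits allow, and the list was not called with an estimated correlation (adjusted p = 0.478) or by fry (0.104), so chance was argued against only by this count. The split of replicates 1 and 2 from 3 and 4 called 51 genes and 18 lists, which points to a structure of the samples that crosses the groups. With a term for that structure 2 genes were called, Gm8430 and, higher in BPA, mt-Tn.

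A single library lay far from the other 3 of its group in 31 of 342 groups of 4 values, where chance gives about 1 in 20. BPA replicate 4 held 13 of these. Its first principal component score was 57.5 (others -4.70 to 4.08). Its mitochondrial share of reads was 14.2% (9.66 to 9.85%), and its share of Kap, an androgen-regulated kidney transcript, was 2.05% (4.14 to 4.34%). Mean log2 levels were 5.74 for oxidative phosphorylation (6.52 to 6.62), 10.8 for mitochondrially encoded transcripts (9.86 to 9.96), 2.10 for histones (2.68 to 2.74), 3.90 for the unfolded protein response (3.99 to 4) and 1.34 for lymphocytes (2.27 to 2.40). In FPKM, Zfp771 was at 8.86 (11.6 to 12.1), mt-Nd1 at 18354 (14166 to 14780), Nat8 at 88.9 (167 to 181), Atp6v0d2 at 17.0 (10.4 to 11.1) and Cd8a at 1.70 (0.135 to 0.195).

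Vehicle replicate 4 held 5: skeletal muscle at a mean log2 of 4.84 (0.726 to 0.813), lymphocytes at 3.34 (2.01 to 2.23), Actn3 at 16.6 FPKM (0.0773 to 0.208), Hsd11b1 at 131 FPKM (41.0 to 53.5) and Srf at 9.34 FPKM (11.5 to 11.7). Vehicle replicate 2 was apart in Havcr1 at 3.12 FPKM (1.40 to 1.68), Cebpb at 10.5 FPKM (24.0 to 25.2), Ccnd1 at 28.1 FPKM (15.5 to 17.0) and mitochondrial share at 8.33% (7.02 to 7.19%). Vehicle replicate 3 was apart in genes above 0, 19693 (20696 to 20845), and in the transporter Slc22a29 at 0.142 FPKM (0.505 to 0.517). Vehicle replicate 1 was apart in Igtp at 6.56 FPKM (9.06 to 9.27) and Slc3a1 at 165 FPKM (189 to 193). BPA replicate 3 was apart in Hsd3b4 at 0.975 FPKM (6.01 to 6.27) and fibroblast markers at a mean log2 of 1.962 (2.30 to 2.35). BPA replicate 1 was apart in Gsto1 at 7.47 FPKM (6.18 to 6.40) and Gclc at 102 FPKM (90.5 to 92.3), and BPA replicate 2 in Ccl21a at 0.147 FPKM (0 to 0).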

How the results depend on the processing

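The term for replicates 1 and 2 against 3 and 4, the clock covariate, the GC correction and leaving out both replicates 4 were chosen after seeing the data.

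The count of called genes (1) was 8 with library weights, 2 with the term for replicates 1 and 2 against 3 and 4, 0 with limma-voom on recovered reads (1507 at an unadjusted p under 0.05), 0 with protein-coding genes only (1349), where Gm8430 is left out by construction, and 0 to 4 when each library was left out (0 without vehicle replicate 1, 4 without BPA replicate 3). List members called (0) were 2 with library weights and 0 to 2 when each library was left out (2 without BPA replicate 3). Lists called (16) were 0 by camera with an estimated correlation and 0 by fry, and 9 without BPA replicate 2 to 20 without vehicle replicate 3. The immediate early list, whose median of -0.46 does not depend on the test, was not called with an estimated correlation (adjusted p = 0.478) or by fry (adjusted p = 0.104). For changes with no reason given here the cause was not tested.

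With the replicate block limma called 0 genes (1376 at an unadjusted p under 0.05; Gm8430 adjusted p = 0.196). Same-numbered libraries had correlations of 0.137, 0.019, 0.138 and -0.033, and not every library correlated best with its own number, so the numbers were not taken as pairs.

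The steroid hormone list turned to -0.0111 without a filter, -0.0356 at a mean of at least 5 FPKM, -0.0222 after rescaling to a common total, and -0.0250 to 0.0886 when each library was left out. Krt7, a urothelial marker, ran from -0.263 to 0.0828, Ddx3y turned to -0.0344 after GC correction, and Hsd11b1 to 0.25 without both replicates 4. The skeletal muscle list was at 0 without both replicates 4 and at -1.47 to 0 when each library was left out, since vehicle replicate 4 held its signal. It had too few members for a test at a mean of at least 5 FPKM. Of 2841 values of 111 named genes under 26 alternatives, 2822 kept direction and side of the threshold, 10 came to pass it, 6 lost it and 3 turned. Only Gm8430 was called in the main test, so keeping the side mostly means staying uncalled and says nothing of the size of a change. Scaling to a common total moved the median of all genes to -0.0712.

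Of 31 other lists not called, 830 values under the alternatives were 732 unchanged, 33 that came to be called, over 11 lists, and 65 that turned, over 20 lists. With the replicate block the calls gained were xenobiotic phase I (adjusted p = 0.0479), female-biased (0.0355) and thick ascending limb (0.0416). Of the values that turned, 1 was called: lymphocyte markers, from -0.334 to 0.307 without both replicates 4 (adjusted p = 0.00853).

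Without a filter the median turned to -0.0152 for adrenal cortex and -0.0812 for adrenal medulla. The p53 list turned to -0.0656 at a mean of at least 5 FPKM and -0.0357 after rescaling to a common total. Quantile normalization turned interferon-stimulated genes to 0.00936, aldosterone genes to 0.0475, androgen-responsive genes to 0.00326, amino acid metabolism to 0.0468 and gluconeogenesis to 0.0570. Library weights turned phase II enzymes to 0.0169, cytokines to 0.0234, interferon-stimulated genes to 0.0144, distal convoluted tubule to -0.145, macrophages to 0.0562 and lymphocytes to 0.0247. GC correction turned cytokines to 0.00505, aldosterone genes to 0.112, gluconeogenesis to 0.0812, intercalated cells to 0.0514 and adrenal medulla to -0.0148. Leaving out both replicates 4 turned hormone receptors to -0.00328, phase II enzymes to 0.0466, cytokines to 0.00165, interferon-stimulated genes to 0.0370, androgen-responsive genes to 0.0982, amino acid metabolism to 0.0200, distal convoluted tubule to -0.158, macrophages to 0.174 and thick ascending limb to -0.0344.

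When each library was left out, these medians crossed 0: aldosterone genes -0.126 to 0.122, p53 -0.0325 to 0.0353, fatty acid synthesis -0.150 to 0.0387, interferon-stimulated genes -0.0943 to 0.0589 and clock genes -0.247 to 0.106. So did androgen-responsive genes (-0.160 to 0.0584), amino acid metabolism (-0.0865 to 0.0119), gluconeogenesis (-0.0361 to 0.0236), phase II enzymes (-0.116 to 0.0379), NRF2 targets (-0.148 to 0.00896) and cytokines (-0.144 to 0.00317). Among markers the ranges were -0.178 to 0.0424 for principal cells, -0.178 to 0.0141 for intercalated cells, -0.0141 to 0.431 for thick ascending limb, -0.350 to 0.0870 for macrophages, -0.0731 to 0.136 for distal convoluted tubule and -0.00158 to 0.268 for adrenal medulla.

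Over the alternatives other than single libraries, further lowest or highest medians of the lists not called were these. Rescaling gave the lowest for tubule injury (-0.205), NRF2 targets (-0.159), cytokines (-0.153), phase II enzymes (-0.133), androgen-responsive genes (-0.131), amino acid metabolism (-0.109), fatty acid oxidation (-0.162), fatty acid synthesis (-0.131), gluconeogenesis (-0.0691), hypoxia (-0.128) and lymphocytes (-0.451). Without a filter were the lowest for phase I enzymes (0.0631), cell cycle (0.0370), fibroblasts (0.0780) and liver (0.0728). A mean of at least 5 FPKM gave the lowest for female-biased genes (0.0395), interferon-stimulated genes (-0.278) and macrophages (-0.220). Quantile normalization gave the highest for phase I enzymes (0.223), female-biased genes (0.287), transporters (0.201), straight proximal tubule (0.201), thick ascending limb (0.313), fatty acid oxidation (-0.0112) and hypoxia (-0.00134). Limma-voom gave the highest for fibroblasts (0.230), liver (0.629) and adrenal cortex (0.388) and the lowest for histones (-0.237). The straight segment was lowest after GC correction (0.0153), and transporters (0.0702) and clock genes (-0.2) with library weights.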

Other observations

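The test of REV-ERB targets was chosen only after the result was seen, as were the genes named here.

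With both groups pooled, replicates 3 and 4 differed from replicates 1 and 2 in 51 genes, 21 higher and 30 lower, by limma at an adjusted p under 0.05. Besides the clock activators Arntl (log2 difference -1.74) and Npas2 (-2.65), the repressor Ciart (2.36) and the output genes Dbp (2.86), Tef (1.18) and Usp2 (1.51), they included Plvap, of fenestral diaphragms (-1.47), the transcription factor Sox18 (-1.19), the proteoglycan gene Esm1 (-1.90) and the vasopressin receptor Avpr1a (-1.2). The difference was not tested within each group, and no gene group was tested among them. The division was first seen in clock genes of these data, so for clock genes the adjusted p restates that choice.

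Within this structure, the clock repressor gene Nr1d1, which encodes REV-ERB alpha, had a BPA change of 1.2, and Cry1 (-1.2) and Nfil3 (-1.07), which it represses, were lower (limma adjusted p = 0.365, 0.271 and 0.387, none passing). Stronger repression by REV-ERB may link them, and the further targets Arntl, Npas2 and Clock had changes of -0.39, -0.28 and 0.21, a median of -0.280. That value lies between what the hypothesis needs and what would exclude it, so it cannot be told apart from no such link.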
